A study of Mus musculus with 6 samples.

How the data were processed

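The values are those deposited by the authors on the log2 scale, and the submitters' processing notes name RMA and the R package affy, with no version, order or settings. Background correction, any filter and a genome build are not given in the sources used here. All 6 arrays held the same 7077 distinct values, from 1.85 to 13.3, so a step common to the arrays gave each of them the same set of values. Column medians over the tested probe sets nevertheless differed, at 6.12, 6.10 and 6.10 for the GV and 5.49, 5.47 and 5.49 for the MII arrays, a difference between stages of -0.62. The table covered part of the array, and the rule that kept its probe sets is not given in the sources used here, so it stays unknown whether that rule or a change in total mRNA set these medians apart. The values were not centred per probe set, and no further step was applied to them for the values given as deposited. The design text states 3 biological replicates per stage, each of 300 oocytes, and 1 array was made of each. Labelling used 2 rounds of amplification with a mixed primer set in place of oligo(dT) and random hexamers.

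Of 21702 probe sets, 56 control features were set aside and 21646 were tested without an intensity filter, of which 19078 had 1 gene symbol, 550 several and 2018 none. The symbols followed the probe table and a RefSeq gene table of GRCm38.p6, used for names alone; 43 of 11429 genes were not in it and 0 symbols needed updating. Each gene was represented by the probe set with 1 symbol and the highest mean over all samples, with the adjusted p of the fit over all probe sets. Several probe sets existed for 4739 genes, and in 513 of them probe sets were called in opposite directions. Ccnb1 and Gapdh had no usable probe set with 1 symbol and were not analysed here as genes, and Hprt1 is named Hprt.

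MII was compared with GV by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, 2-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. The prior added 5.78 degrees of freedom, for a total of 9.78. Stability was tested by 2 one-sided moderated tests against bounds of 1.5-fold, the larger p adjusted by Benjamini-Hochberg over the 10823 probe sets whose mean was above the median of all probe sets (5.85), and bounds of 2-fold were an alternative. Gene lists were tested with limma's camera at its preset correlation of 0.01, on 1 probe set per gene against all other genes, with Benjamini-Hochberg adjustment over 32 lists, beside camera with an estimated correlation and fry. Control features were compared with exact permutation tests, whose smallest p for 3 against 3 samples is 0.1. The analysis was tested on simulated data of 21646 probe sets with known changes: 62.0% of 2-fold and 93.0% of 4-fold changes were recovered, 0% of calls had the wrong sign, 5.49% of calls were of unchanged probe sets, 96.2% of unchanged tested probe sets were called within 2-fold, and 3 probe sets changed by 2-fold or more were. Few of the simulated probe sets were changed, equally upward and downward, unlike the calls in the oocytes, so these rates need not carry over. In the simulated data 0 lists were called by camera with no list effect, and a shifted list was called. The simulated probe sets varied independently of each other, so this could not test camera's preset correlation.

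The tests of the comparison, the 32 lists, the rule for naming genes and the alternatives were set before the data were examined, except for the poly-A scaling and for the tests and groups said elsewhere to be chosen after the data were seen. The rule named the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, no overlap between stages and a mean above the median in the higher stage, leaving out clone names (0 were passed over). It also named in each list up to 2 called members with the largest rise and up to 2 with the largest fall, or the 2 with the highest mean where none was called. Ccnb1, Cdk1, Mos, Gdf9, Bmp15, Zp2, Zp3, Plat, Dazl, Gpr3, Pde3a, Nlrp5, Gapdh, Actb and Hprt were named whatever their values. This gave 139 genes, 59 called higher, 70 lower and 10 not called, and 23 of the called genes had a probe set called the other way.

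The lists, compiled from general knowledge, covered oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, translation factors, proteasome, glycolysis, pyruvate dehydrogenase and TCA cycle, mRNA deadenylation and decay, mRNA storage and translational control, mRNAs known to be recruited to polysomes in maturation, maternal effect genes, oocyte growth factors with zona and oocyte transcription factors, sperm binding and egg activation, cAMP and meiotic arrest, MPF with cytostatic factor and APC/C, spindle with kinetochore and cohesion, DNA replication, DNA repair, RNA polymerase II and general transcription factors, pre-mRNA splicing, chromatin modifiers, nuclear pore and nuclear transport, chaperones and chaperonin, TGF-beta, activin and BMP signalling, MAPK signalling, PI3K, insulin and mTOR signalling, and Wnt signalling. For other cell types they covered granulosa and cumulus cells, cumulus expansion and luteinization, theca and ovarian stroma, blood and immune cells, and oviduct epithelium.

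Alternatives changed 1 choice at a time, except that the intensity trend and robust moderation were changed together. They were 3 scalings between arrays (each array's median subtracted, quantile normalization, and the mean of 18 hybridization control probe sets made equal), leaving out dim probe sets or the 2932 probe sets whose type marks a match to several transcripts, an intensity trend with robust moderation, an ordinary linear model with no moderation, array weights, the replicate number as a block, each sample left out in turn, a threshold of 0.01, 2-fold equivalence bounds, the mean over a gene's probe sets, and the other list tests. A scaling that made the mean of 21 poly-A control probe sets equal was chosen after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Raw intensity files were not used here.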

Results

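Gene expression was measured in mouse oocytes before and after meiotic maturation, with 3 biological replicates of 300 oocytes at each stage. Fully grown oocytes at the germinal vesicle (GV) stage are arrested in the prophase of meiosis, with an intact nucleus. They were taken from large antral follicles of mice aged 22 to 24 days, 44 to 46 h after 5 IU of equine chorionic gonadotropin, a hormone that drives follicle growth. Milrinone at 5 µM, which blocks the oocyte's cyclic AMP phosphodiesterase, kept them from resuming meiosis. Oocytes at metaphase of the second meiotic division (MII) had completed maturation and extruded a polar body, and were collected from oviducts 14 h after a further injection of 5 IU of human chorionic gonadotropin, which triggers maturation and ovulation. From each sample 10 ng of total RNA was amplified over 2 rounds and hybridised to 1 short-oligonucleotide array. The values are log2 expression values for 21702 probe sets, of which 56 were control features and 21646 were tested, and the number of arrays limits their precision. Across probe sets, which are not independent replicates, arrays of the same stage correlated at 0.988 to 0.991 and arrays of different stages at 0.885 to 0.906.

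The comparison addressed which transcripts change and which stay stable as the oocyte matures. Lower transcripts at the MII stage included 39 of 41 measured cytosolic ribosomal protein genes, 56 of 70 genes of oxidative phosphorylation and 64 of 73 mitochondrial ribosomal protein genes. By limma's camera these lists differed from the other genes at Benjamini-Hochberg adjusted p of 1.8e-13, 3.5e-10 and 1.3e-09, a call lost for each at adjusted p = 0.45 with an estimated correlation. Transcripts of the zona pellucida, the oocyte's glycoprotein coat, fell steeply, with log2 differences of -4.26 ± 0.14 for Zp2 and -2.76 ± 0.15 for Zp3 (SE, 3 samples per stage). Zfp57, a zinc finger protein that maintains imprints in the embryo, rose at least 3.13-fold, to near the top of the arrays' range, and Uchl1, a deubiquitinating enzyme abundant in oocytes, rose 2.93-fold. Gdf9, an oocyte growth factor, differed by 0.09 ± 0.15 and Dazl, an RNA-binding translational regulator, by -0.03 ± 0.16 (for Gdf9 0.71 and called higher with array medians made equal, -0.32 with hybridization controls made equal, -0.79 and called lower with poly-A controls made equal; for Dazl 0.60 with array medians made equal, 0.28 after quantile normalization, 0.13 without MII replicate 2, and -0.90 and called lower with poly-A controls made equal).

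Among the 21646 probe sets, 2358 were higher and 7376 were lower in MII oocytes by limma at a Benjamini-Hochberg adjusted p under 0.05, so that 75.8% of the calls were falls. Changes of at least 2-fold were called for 332 probe sets in the upward and 4454 in the downward direction. At 4-fold or more, 2 probe sets were higher and 1909 lower. The steepest fall was at least 149-fold, to an MII value of 4.24, and the steepest rise at least 5.79-fold. The 3 GV and 3 MII values did not overlap for 11688 probe sets (54.0%), where chance gives 10%. With 1 probe set per gene, 1204 of 11429 genes rose and 4315 fell, 148 and 2641 of them by at least 2-fold. The median log2 difference over all probe sets was -0.15. These counts rest on the scale between arrays as deposited: with array medians made equal, which shifted the median difference by 0.62, 12016 probe sets were higher and 4306 lower. After quantile normalization (a shift of 0.34) the split was 7538 higher and 4794 lower, and with the hybridization controls made equal (a shift of -0.41) it was 104 higher and 7179 lower, while leaving out GV replicate 2 lowered the number of higher probe sets to 1547. The hybridization controls differed among the GV arrays (SD 0.50), so making them equal added spread within that stage and can end calls by itself. None of the probe sets called lower as deposited was called higher in any of these 3 scalings, and none turned from higher to lower. With the poly-A controls made equal, a scaling chosen after seeing the data (a shift of -0.87), 65 probe sets were higher and 18380 lower, and 21 of those higher as deposited were called lower. Of 62 genes named here with a difference above 0, that scaling left 15 called higher and put 28 below 0, while all 70 named falls were still called, and falls outnumbered rises in each of the 32 gene lists.

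**Figure D1:**
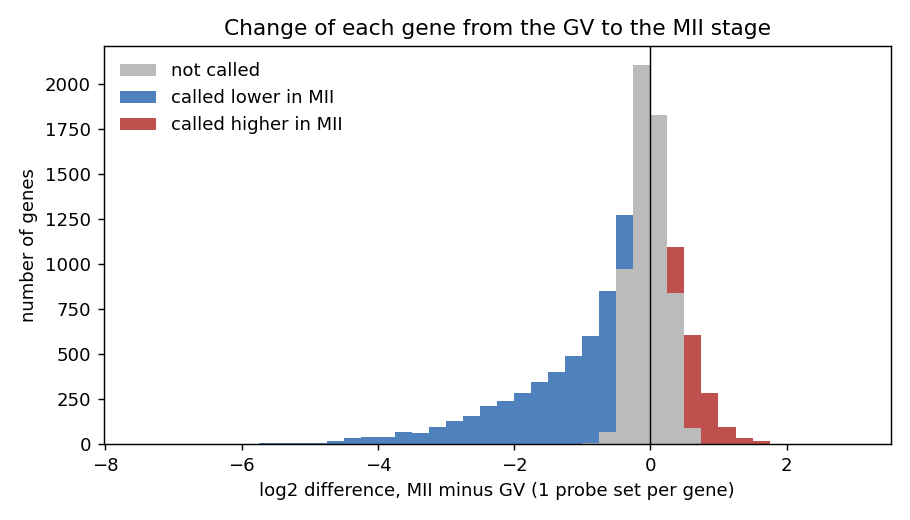
Histogram of the log2 difference (MII minus GV, x axis) of 11429 genes with the number of genes on the y axis, coloured by the limma call on the values as deposited. The 4315 genes called lower form a long tail to the left, and the 1204 genes called higher stay close to 0. Among probe sets, which side holds more calls turns when array medians are made equal or the arrays are quantile normalized.

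**Figure D2:**
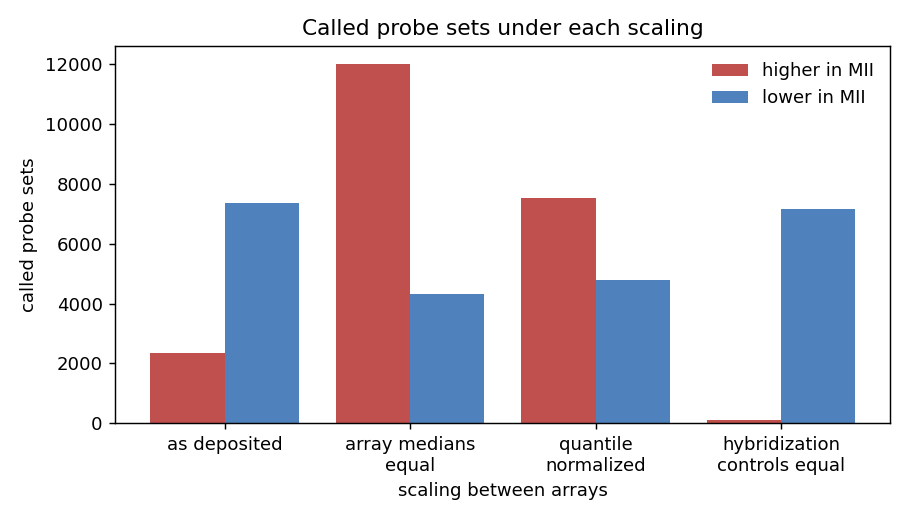
Number of probe sets called higher (red) and lower (blue) in MII oocytes (y axis) under 4 scalings between arrays (x axis), without the poly-A scaling. Among these 4, lower calls range from 4306 to 7376, whereas higher calls range from 104 to 12016 and outnumber the lower ones with equal array medians and after quantile normalization.

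The steepest fall among the named genes was that of Ppil3, a cyclophilin-type prolyl isomerase, which fell by 6.77 ± 0.15 on the log2 scale (SE), which is at least 109-fold, from 10.43 ± 0.19 to 3.66 ± 0.16 (SD, n = 3). Psmd14, the deubiquitinase of the proteasome lid, fell at least 75.4-fold and Polr2b, a core subunit of RNA polymerase II, at least 68.8-fold. Zfp839, a zinc finger gene, fell at least 62.9-fold, and Tmsb10, which binds actin monomers, at least 62.1-fold. Of the 12 steepest falls 9 ended below the median of every MII array (5.47 or more), all but those of Tuba4a, Elp2 and Bud31, and since no measure of background was used here, their folds are given as lower bounds. The other falls, as log2 differences, were those of Supt20 (-5.83), the alpha tubulin gene Tuba4a (-5.77), the transketolase gene Tkt (-5.70), the Elongator subunit gene Elp2 (-5.67), the splicing factor gene Bud31 (-5.56), the cyclin H gene Ccnh (-5.54) and the respiratory chain gene Ndufa2 (-5.50). Adjusted p ranged from 7e-09 to 2.8e-08 over these 12 genes (limma, Benjamini-Hochberg), and each kept its fall in the 3 other scalings. Elp2 had a GV mean of 13.12, near the top of the arrays' range, so its fall is a lower bound as well. For Supt20 and Ccnh another probe set was called higher in MII, and without the probe sets taken as matching several transcripts the brightest probe set left was at 0.55 for Supt20 (another was at -2.14 and called lower), 0.31 for Elp2 and -0.24 for Bud31. Other probe sets were at -3.28, -1.09 and -0.74 for Tmsb10, -2.91 and -0.28 for Tkt and -2.56 for Tuba4a, so the folds given hold for the brightest probe set alone. The only probe set of Ndufa2 and all those of Tmsb10 were of the types _s_at or _x_at, taken as matching several transcripts, whether or not of the same gene.

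Rises were smaller. Ly6e, a cell surface protein, rose by 2.53 ± 0.16 (SE; at least 5.79-fold), from 5.94 ± 0.23 to 8.47 ± 0.16 (SD, n = 3), and Clybl, a mitochondrial lyase, by 2.02 ± 0.15. Zfp57 rose by 1.65 ± 0.18, to 13.07 ± 0.03 (SD), near the top of the arrays' range, which makes its rise a lower bound. Letmd1 and Ubn1 both rose by 1.75, Rdh9 by 1.74, the neuronal intermediate filament gene Ina by 1.72, the transcription factor gene Nfix by 1.67, Emsy and Gcnt2 by 1.62, the seryl-tRNA synthetase gene Sars 3.03-fold and Terb1, which joins meiotic telomeres to the nuclear envelope, by 1.59. Adjusted p ranged from 6.8e-07 to 0.0048 (limma, Benjamini-Hochberg), and all 12 kept their rise in the 3 other scalings. Ina, Gcnt2, Sars and Terb1 had another probe set called lower, and the mean over probe sets was -0.30 for Sars and -1.42 for Terb1. Probe sets not called were at -0.11 for Ubn1, 0.16 and 0.09 for Emsy and -0.31 for Nfix, whose others were called higher. Ly6e, Letmd1, Rdh9, Nfix and Gcnt2 started below the median of every GV array (6.10 or more), so their rises are lower bounds in the same way. With no moderation of the variance, the rises of Ubn1, Emsy, Gcnt2 and Terb1 were no longer called.

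Genes for protein synthesis, folding and turnover and for respiration fell more often than they rose. As groups, 5 of these 6 lists were called by limma's camera, each at a Benjamini-Hochberg adjusted p = 0.45 with an estimated correlation, and translation factors were not called (adjusted p = 0.084). Among ribosomal proteins, Rps20 was at -5.41 and Rpl10a at -4.71 (log2), and in mitochondrial ribosomes Mrpl48 was at -4.28 and Mrps18c at -4.25, while 2 members rose, Mrpl38 by 1.09 and Mrpl40 by 0.57 (0.50 and not called without MII replicate 2 or 3). In oxidative phosphorylation, Ndufa2 and Ndufa9 of the NADH dehydrogenase were at -5.50 and -5.47, against rises of 0.98 for Sdhd and 0.54 for Cox8a, among the 3 members that rose. Of 36 proteasome genes 25 fell, with Psmd14 at -6.24 and the ATPase gene Psmc2 at -5.45, and 3 rose, led by Psmd1 at 1.36 and Psmd3 at 0.68. Of 34 chaperone genes 25 fell, with Hsph1 at -5.36 and Dnajb6 at -4.88, and 2 rose, Hsp90b1 by 1.04 and Hspa14 by 0.63. Among 39 translation factors 24 fell and 5 rose, with Eif1ax at -5.19, Eif2b4 at -4.34, a 2.38-fold rise of the poly(A)-binding protein gene Pabpc4, and Eif3i at 0.93. Adjusted over the list alone, 58 oxidative phosphorylation genes fell and 3 rose, 41 ribosomal, 64 mitochondrial ribosomal, 25 proteasome, 25 chaperone and 24 translation factor genes fell, and the rises numbered 2 for mitochondrial ribosomes, 4 for the proteasome, 3 for chaperones and 7 for translation factors. The falls outnumbered the rises in each of these 6 lists under all 5 scalings, the closest being 20 falls and 13 rises for translation factors with equal array medians. Of 10 granulosa and cumulus markers 7 were lower in MII as well, while 0 of 9 genes of cumulus expansion were called by limma (0 unadjusted, 0 with no moderation). However, 0 of these 9 genes had a mean above the median of all probe sets, so their missing calls may reflect weak signal.

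With camera's preset correlation in limma, the 5 called lists differed from the other genes at Benjamini-Hochberg adjusted p of 1.8e-13 for cytosolic ribosomal proteins, 3.5e-10 for oxidative phosphorylation, 1.3e-09 for mitochondrial ribosomal proteins, 0.00089 for chaperones and 0.002 for the proteasome. None of the 5 calls held when camera estimated the correlation within each list. Translation factors had a limma camera adjusted p (Benjamini-Hochberg) of 0.003 with equal array medians, 0.0043 after quantile normalization and 9.8e-05 with either set of controls made equal, and 0.45 with an estimated correlation. In the same order, the median log2 differences were -2.48, -1.80, -1.57, -1.07 and -1.04, and -1.20 for translation factors. Another probe set of Sdhd and of Hsp90b1 was called lower. Probe sets not called were at 0.21 for Eif1ax, 0.32 for Dnajb6 and -0.30 for Mrpl48. With hybridization controls made equal, the rises named for these lists were no longer called except that of Psmd1, and with no moderation those of Mrpl40, Psmd1 and Hsp90b1 were not.

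**Figure D3:**
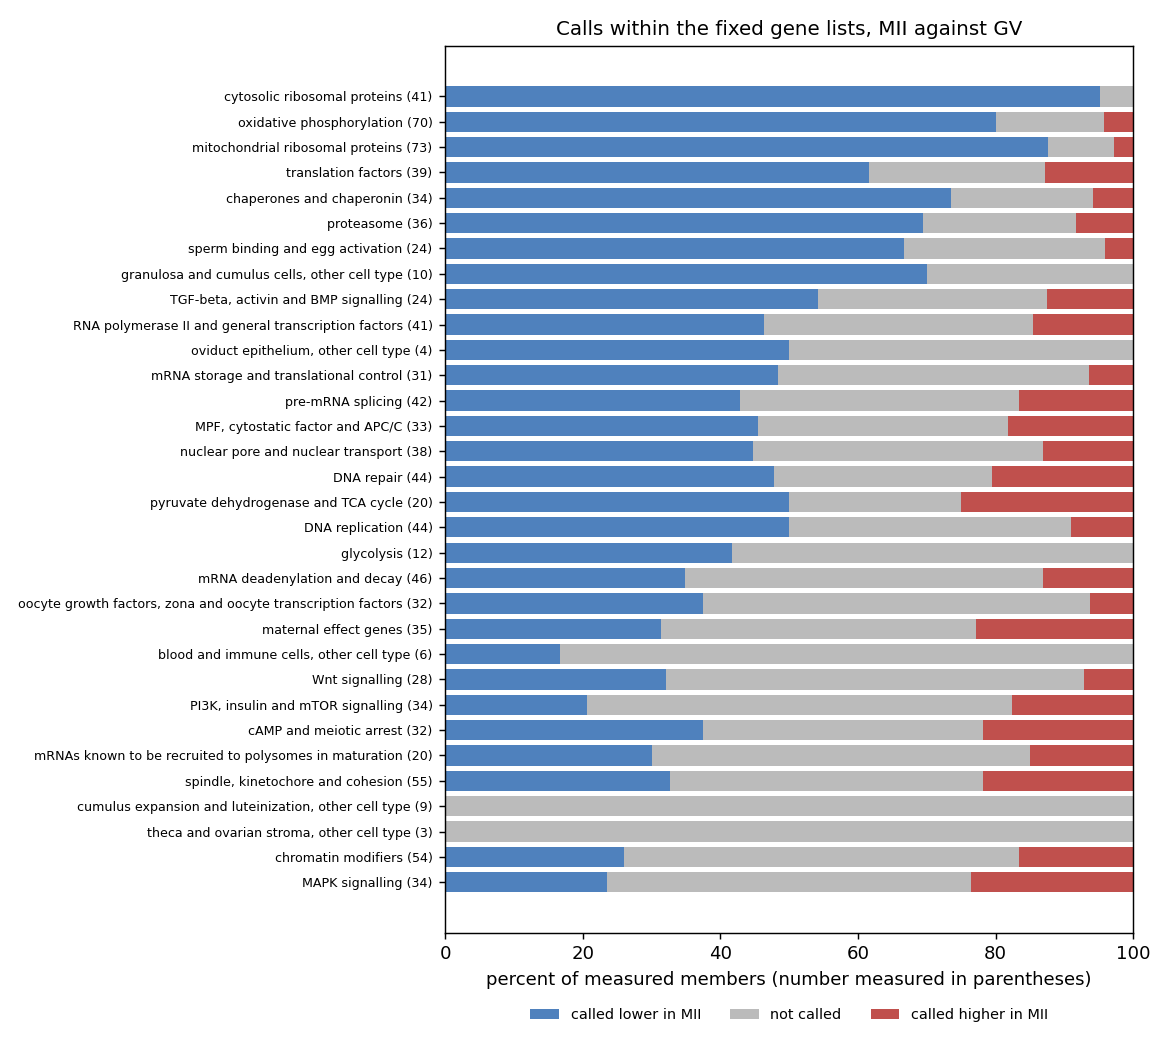
Percent of the measured members of each of 32 gene lists (y axis, with the number measured) called lower in MII (blue), not called (grey) or called higher (red) by limma on the values as deposited, ordered by the list's median log2 difference. Falls fill 39 of 41 cytosolic ribosomal protein genes and 8 of 34 genes of MAPK signalling; with equal array medians, rises outnumber falls in every list but those 6 of protein synthesis, folding, turnover and respiration, egg activation, and granulosa and cumulus cells.

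Oocyte-specific and maternal genes divided between steep falls, rises and small differences. Of 32 genes for oocyte growth factors, zona and oocyte transcription factors, 12 fell and 2 rose (10 and 17 with equal array medians, 11 and 7 after quantile normalization, 12 falls with equal hybridization controls). Besides Zp2 and Zp3, the connexin 37 gene Gja4, which couples the oocyte to cumulus cells, fell by 3.46, whereas the growth factor gene Bmp15 rose by 0.69 ± 0.17 and the oocyte linker histone gene H1f8 by 0.66 ± 0.21. Other probe sets of Bmp15 were at -0.22 and -0.33, neither called. Of 35 maternal effect genes, whose products the embryo needs, 11 fell and 8 rose (9 and 21 with equal array medians, 9 and 15 after quantile normalization, 11 and 2 with equal hybridization controls). Khdc3 was at -3.48 and the maintenance methyltransferase gene Dnmt1 at -2.30, both called lower, against the rises of Zfp57 and Uchl1. Nlrp5, another maternal effect gene, differed by -0.30 ± 0.15 (0.32 with equal array medians, -1.18 and called lower with equal poly-A controls). Of 24 genes for sperm binding and egg activation 16 fell and 1 rose, with falls outnumbering rises in all 5 scalings. The calcium channel gene Orai1 was at -2.79, Nsf at -2.68, and the calcium-dependent kinase gene Camk2g rose by 0.99, although another probe set of Nsf was higher and of Camk2g lower. The falls and rises adjusted over the list alone were 12 and 2 for the oocyte list, 12 and 8 for maternal effect genes and 17 and 1 for egg activation. By limma's camera the Benjamini-Hochberg adjusted p of these lists was 0.68, 0.66 and 0.13. Bmp15, H1f8 and Camk2g were no longer called with equal hybridization controls, and H1f8 lost its call without GV replicate 1 or 3 or MII replicate 2 or 3 (0.52 to 0.65) and with no moderation.

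Genes that control meiotic progression went both ways. Cdk1, the kinase of maturation promoting factor, differed by -1.53 ± 0.15, and Mos, the kinase upstream of cytostatic arrest, by -1.30 ± 0.16, with both falls called in every scaling. Of 33 genes of these factors and the anaphase promoting complex, 15 fell and 6 rose (8 and 15 with equal array medians, 8 and 10 after quantile normalization, 15 falls and no rise with equal hybridization controls). Anapc7 was at -4.47, Anapc2 at -2.98, Anapc11 at 0.99 and Cks2 at 0.82. Of 32 genes of cyclic AMP signalling and meiotic arrest, 12 fell and 7 rose (9 and 19 with equal array medians, 10 and 16 after quantile normalization, 12 falls and no rise with equal hybridization controls). The phosphatase genes Cdc25c and Cdc25a, which activate Cdk1, were at -3.02 and -2.60. The other probe set of Cdc25a was at 0.11 and that of Anapc7 at 0.05, neither called. The protein phosphatase gene Ppp1ca rose by 1.13 and the protein kinase A gene Prkaca by 0.81. The Prkaca probe set was of a type taken as matching several transcripts, and the other probe set of Prkaca was at 0.41 and not called. Gpr3, the receptor that keeps cyclic AMP high, differed by -0.47 ± 0.20 (0.15 with equal array medians, 0.13 after quantile normalization). It was at -0.25 without GV replicate 1, and was called lower without GV replicate 3 (-0.65) and with equal poly-A controls (-1.34). Pde3a, the phosphodiesterase, differed by 0.24 ± 0.19 (0.86 and called higher with equal array medians, 0.79 and called higher after quantile normalization, -0.17 with equal hybridization controls, and -0.64 and called lower with equal poly-A controls). Among 55 spindle, kinetochore and cohesion genes 18 fell and 12 rose (16 and 32 with equal array medians, 16 and 28 after quantile normalization, 18 falls and no rise with equal hybridization controls). They included the spindle protein gene Tacc3 at -5.19, the checkpoint kinase gene Bub1 at -3.63, Racgap1 at 0.83 and the kinesin gene Kif23 at 0.69. These 3 lists held 16 and 6, 12 and 9, and 19 and 13 falls and rises adjusted over the list alone. Their adjusted p by limma's camera (Benjamini-Hochberg) was 0.81, 0.68 and 0.68. Other probe sets of Anapc11 and Racgap1 were called lower, and with equal hybridization controls the rises named here were no longer called, nor was that of Kif23 without GV replicate 2 (0.53) or MII replicate 2 (0.58). With no moderation Prkaca and Kif23 were not called.

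**Figure D4:**
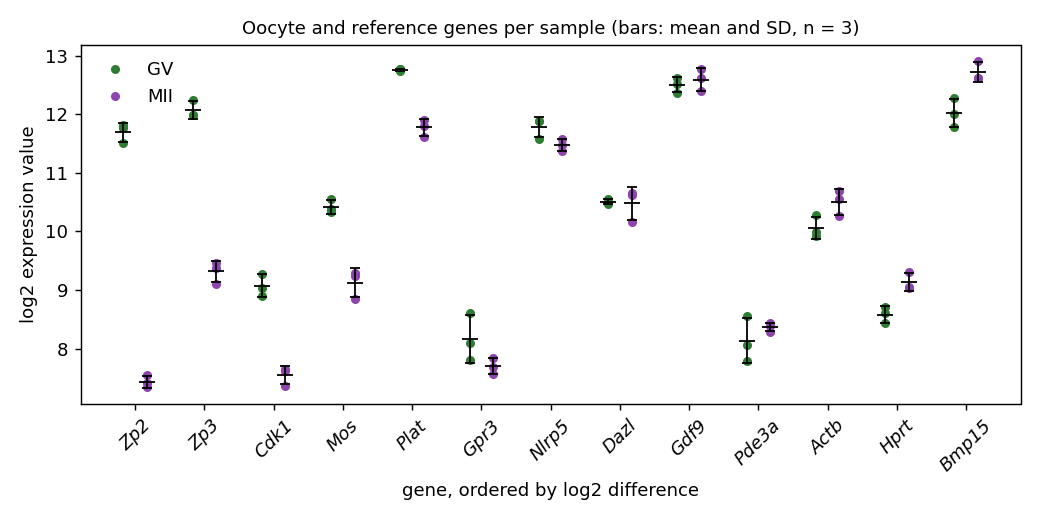
Log2 expression values (y axis) of 13 genes chosen before the data were examined (x axis), 1 point per sample, with the mean and SD of 3 GV (green) and 3 MII (purple) samples. Zp2, Zp3, Cdk1, Mos and Plat are lower in MII in every scaling, Hprt and Bmp15 are higher as deposited, and the small differences of Gpr3, Nlrp5 and Dazl (with equal array medians, Gpr3 and Dazl also after quantile normalization) and of Gdf9 and Pde3a (with equal hybridization or poly-A controls) change sign, as do those of Hprt, Bmp15 and Actb with equal poly-A controls.

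Among transcripts for handling stored messages more fell than rose as deposited, and more rose than fell with equal array medians. Among 20 messages known to move onto polysomes during maturation, 6 fell and 3 rose (5 and 14 with equal array medians, 6 and 8 after quantile normalization, 6 falls and no rise with equal hybridization controls). Cdc6 was at -3.71, Bub1 at -3.63 and the tissue plasminogen activator gene Plat at -0.98 ± 0.14, and Racgap1 and the spindle gene Tpx2 rose by 0.83 and 0.48. Of 46 genes for deadenylation and decay of messages, 16 fell and 6 rose (9 and 24 with equal array medians, 9 and 16 after quantile normalization, 16 falls and no rise with equal hybridization controls). Among them were the antiproliferative genes Tob1 at -4.18 and Tob2 at -3.25 and the deadenylase complex genes Cnot8 and Cnot2 both at 0.76. Of 31 genes for storage and translational control, 15 fell and 2 rose (10 and 12 with equal array medians, 10 and 5 after quantile normalization, 15 falls and no rise with equal hybridization controls). They included Paip2 at -4.65, Cpsf4 at -2.48, the poly(A) polymerase gene Tent2 at 0.49 and Marf1 at 0.42. Falls and rises adjusted over the list alone were 6 and 3, 16 and 6, and 16 and 2. Camera in limma gave Benjamini-Hochberg adjusted p of 0.79, 0.90 and 0.38. Tob2 and Cnot2 had probe sets called in both directions, and without the probe sets taken as matching several transcripts the brightest of Tob2 was at 0.44. The rises named here were not called with equal hybridization controls, and 1 sample decided those of Tent2 (0.43 without MII replicate 2), Tpx2 (0.42 to 0.49 without GV replicate 2 or 3 or MII replicate 2 or 3) and Marf1 (0.34 to 0.46 without any 1 of the samples but GV replicate 1). With no moderation Cnot8, Cnot2, Tpx2 and Marf1 were not called.

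Transcription, splicing and chromatin genes showed large single falls within mixed groups. Of 41 genes of RNA polymerase II and its general factors, 19 fell and 6 rose (15 and 18 with equal array medians, 15 and 17 after quantile normalization, 20 falls and no rise with equal hybridization controls), Polr2b and Ccnh at the one end and Taf10 (1.03) and Gtf2a2 (0.72) at the other. Of 42 splicing genes 18 fell and 7 rose (12 and 19 with equal array medians, 13 and 17 after quantile normalization, 20 falls and no rise with equal hybridization controls). Ddx39b was at -4.03, Srsf1 at -3.98, Srsf3 at 0.70 and Snrpg at 0.57. Among 54 chromatin modifiers, 14 fell and 9 rose (6 and 38 with equal array medians, 9 and 30 after quantile normalization, 14 falls and no rise with equal hybridization controls). The acetyltransferase gene Kat8 was at -4.49 and the heterochromatin gene Cbx5 at -2.85, and the methyltransferase gene Kmt2b and the remodeller gene Chd4 rose by 1.00 and 0.95. For this list the median difference was 0.07, the mean -0.22, and limma's camera did not call it (Benjamini-Hochberg adjusted p = 0.13). Of 38 nuclear pore and transport genes 17 fell and 5 rose (11 and 16 with equal array medians, 12 and 11 after quantile normalization, 16 falls and no rise with equal hybridization controls). Nup133 was at -4.27, the lamin gene Lmna at -3.20, Rcc1 at 0.63 and Nup37 at 0.54. Among the falls named here, probe sets not called were at -0.36 and -0.27 for Nup133, -0.25 and 0.26 for Srsf1, and -0.20 and -0.37 for Cbx5. In list order, 19 and 6, 21 and 8, 14 and 9, and 20 and 5 genes fell and rose adjusted over the list alone. For the other 3 lists limma's camera gave Benjamini-Hochberg adjusted p of 0.50, 0.68 and 0.68, although the polymerase list reached 0.014 with equal hybridization or poly-A controls (as deposited, adjusted p = 0.88 with an estimated correlation). Equal hybridization controls ended the calls of all the rises named here, and Nup37 also lost its call without GV replicate 1 or 3 or MII replicate 2 or 3 (0.39 to 0.58) and with no moderation.

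DNA replication and repair genes fell more often than they rose as deposited. Of 44 replication genes 22 fell and 4 rose (18 and 21 with equal array medians, 18 and 18 after quantile normalization, 21 and 1 with equal hybridization controls). Rpa2 was at -4.34, the topoisomerase gene Top2a at -4.08, the polymerase subunit gene Pold3 at 1.42 and the helicase gene Mcm5 at 1.13. Of 44 repair genes 21 fell and 9 rose (16 and 21 with equal array medians, 16 and 19 after quantile normalization, 21 falls and no rise with equal hybridization controls). The Ku subunit gene Xrcc5 was at -4.47, Ercc3 at -3.64, Rad51c at 1.23 and Rad52 at 1.10. Pold3, Mcm5 and Rad51c each had another probe set called lower, and their means over probe sets were -1.44, -0.83 and -0.32. Other probe sets of Rpa2 and Top2a were at -0.33 and -0.32, neither called. Replication held 22 falls and 7 rises adjusted over the list alone, and repair 21 and 10. Limma's camera gave Benjamini-Hochberg adjusted p of 0.75 and 0.90, and of the 4 rises only that of Pold3 was called with equal hybridization controls. In central metabolism, 5 of 12 glycolysis genes fell (5 falls and 7 rises with equal array medians, 5 and 4 after quantile normalization, 5 falls and no rise with equal hybridization controls), among them the pyruvate kinase gene Pkm (-1.83) and the lactate dehydrogenase gene Ldha (-1.77). Of 20 genes of pyruvate dehydrogenase and the citric acid cycle 10 fell and 5 rose (9 and 10 with equal array medians, 9 and 8 after quantile normalization, 9 falls and no rise with equal hybridization controls). Idh3g was at -4.10, Sdhb at -3.26, Sdhd at 0.98 and Suclg2 at 0.88. Adjusted over the list alone, 5 glycolysis genes fell, and 10 genes of the cycle fell and 5 rose. The adjusted p of limma's camera (Benjamini-Hochberg) was 0.69 for glycolysis and 0.71 for the cycle.

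Signalling genes went both ways. In MAPK signalling 8 of 34 genes rose and 8 fell (25 and 5 with equal array medians, 22 and 7 after quantile normalization, 1 and 7 with equal hybridization controls). The p38 kinase gene Mapk14 rose by 1.45 and Mapkapk5 by 0.71, while the adaptor gene Grb2 was at -3.19 and Map3k5 at -2.84. Other probe sets of Mapk14 and Map3k5 were called the other way, and another of Grb2 was at -0.32 and not called. The list's median was 0.17 and its mean -0.16, and limma's camera did not call it (Benjamini-Hochberg adjusted p = 0.072). Of 34 genes of PI3K, insulin and mTOR signalling 6 rose and 7 fell (22 and 3 with equal array medians, 15 and 4 after quantile normalization, 6 falls and no rise with equal hybridization controls). Prkab1 was at 1.08, Rps6kb2 at 0.84, Pik3c3 at -2.26 and Prkag1 at -1.78. Rps6kb2 started at 5.47, below the median of every GV array (6.10 or more), so its rise is a lower bound. Of 24 genes of TGF-beta, activin and BMP signalling 3 rose and 13 fell (10 and 4 with equal array medians, 6 and 4 after quantile normalization, 12 falls and no rise with equal hybridization controls). The activin receptor gene Acvr2b was at 0.91, Ski at 0.59, Zfyve9 at -2.02 and Smad2 at -1.48. Of 28 Wnt signalling genes 2 rose and 9 fell (18 and 4 with equal array medians, 10 and 4 after quantile normalization, 8 falls and no rise with equal hybridization controls). Ctnnbip1 was at 0.94, Csnk1e at 0.72, Csnk2a2 at -1.78 and Znrf3 at -1.53. Rises and falls adjusted over the list alone were 8 and 8, 4 and 7, 4 and 13, and 2 and 9. The last 3 lists had Benjamini-Hochberg adjusted p of 0.32, 0.90 and 0.69 by limma's camera. Ski, Ctnnbip1, Csnk1e and Csnk2a2 had probe sets called in both directions, and Mapk14 alone among the rises named here was still called with equal hybridization controls. Calls that hung on 1 sample were those of Rps6kb2 (0.58 to 0.86 without any 1 sample but MII replicate 1), Ctnnbip1 (0.71 to 0.88 without GV replicate 2 or 3 or MII replicate 2) and Ski (0.45 to 0.57 without GV replicate 2 or 3 or MII replicate 1 or 3), and with no moderation these 3 and Mapkapk5 were not called.

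Markers of granulosa and cumulus cells fell more often than they rose, whereas those of cumulus expansion, theca and stroma were not called as deposited. In GV oocytes 5 of 10 granulosa and cumulus markers, and in MII oocytes 1, were above the median level of all probe sets. Of 10 measured granulosa and cumulus genes 7 fell (3 falls and 2 rises with equal array medians or after quantile normalization, 6 falls with equal hybridization controls), and 7 fell when adjusted over the list alone. The gap junction gene Gja1 fell from 5.97 ± 0.31 to 2.22 ± 0.01 (SD, n = 3), a difference of -3.74 ± 0.17 (SE), and the inhibin subunit gene Inhba fell by 1.40 ± 0.14. For this list limma's camera gave a Benjamini-Hochberg adjusted p of 0.15. Of 9 genes of cumulus expansion and luteinization and of 3 genes of theca and stroma, 0 passed limma's test, and the count was also 0 adjusted over the list alone, at an unadjusted p under 0.05 and in the linear model with no moderation. Their brightest members were Cyp11a1 (-0.45 ± 0.22), Star (-0.13 ± 0.15), Col1a2 (-0.01 ± 0.14) and Mfap5 (-0.13 ± 0.15), and all 4 differences were above 0 with equal array medians, where 7 of the 9 and 3 of the 3 genes were called higher (1 theca and stroma gene after quantile normalization). With poly-A controls made equal, all 4 named genes were called lower. In the cumulus expansion list and in the theca and stroma list 0 genes had a mean above the median of all probe sets. Missing calls in these lists may therefore reflect weak signal. Of 6 blood and immune genes C1qb fell, by 1.42 ± 0.22, and of 4 oviduct epithelium genes Krt8 was at -0.83 ± 0.16 and Cldn4 at -0.71 ± 0.17, both called lower, though neither passed with equal array medians, and Cldn4 did not with no moderation. The count was 1 blood gene and 2 oviduct genes lower adjusted over the list alone. These 4 lists had Benjamini-Hochberg adjusted p by limma's camera of 0.48, 0.69, 0.94 and 0.79, in the order given.

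Stability was tested as equivalence, among the 10823 probe sets brighter than the median of all probe sets. With bounds of 1.5-fold, limma's moderated equivalence test called 0 probe sets stable after Benjamini-Hochberg adjustment, the smallest adjusted p being 0.0515, while 3108 passed at an unadjusted p under 0.05. The count was 530 with an intensity trend and robust moderation, 256 with no moderation and 852 with array weights. With bounds of 2-fold, 5825 probe sets (53.8%) were within 2-fold, of which 1332 were also called changed, so that being within 2-fold does not mean unchanged. The number within 2-fold was 3658 with equal array medians, 4263 after quantile normalization, 1443 with equal poly-A controls and 0 with equal hybridization controls. With 1 probe set per gene, 3630 of 6574 genes (55.2%) were within 2-fold. They included Gdf9 and Dazl (adjusted p = 0.00079 for both, limma, Benjamini-Hochberg), Nlrp5 (0.0017), Pde3a (0.0038), Actb (0.0083) and Gpr3 (0.027). Actb, a common reference gene, differed by 0.44 ± 0.16 with a limma Benjamini-Hochberg adjusted p of 0.055 (called at 0.54 without GV replicate 3 and at 0.56 without MII replicate 2), and Hprt, another, rose by 0.55 ± 0.15, with both called with equal array medians and neither with equal hybridization controls, and below 0 with equal poly-A controls (-0.44 and -0.32). The share within 2-fold was 72.7% of 22 tested genes of PI3K, insulin and mTOR signalling, 68.6% of 35 nuclear pore genes, 66.7% of 36 decay genes, 65.4% of 52 spindle genes and 65.0% of 20 messages known to move onto polysomes. It was 23.0% of 61 oxidative phosphorylation genes, 20.0% of 55 mitochondrial and 8.57% of 35 cytosolic ribosomal protein genes.

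Control features on the same arrays also differed in level. The 18 probe sets for hybridization controls, added after labelling, averaged 9.24 ± 0.50 on GV and 9.65 ± 0.22 on MII arrays (SD, n = 3), a difference of 0.40 (2-sided exact permutation p = 0.3), with GV replicate 1 at 9.82 and the other GV arrays at 8.97 and 8.94. The 21 probe sets for poly-A controls averaged 4.43 ± 0.24 and 5.31 ± 0.15, a difference of 0.87 (2-sided exact permutation p = 0.1, the smallest that 3 against 3 samples allow). The difference was positive for all 21 probe sets, as it was for all 18 of the hybridization controls, and probe sets of 1 control transcript are not independent. Signal at the 3' end of the Gapdh control transcript exceeded that at its 5' end by 2.81 ± 0.20 on GV and 2.25 ± 0.33 on MII arrays (exact permutation p = 0.1), and for the Actb control the excess was 0.51 ± 0.40 and 0.49 ± 0.37 (exact permutation p = 1).

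**Figure D5:**
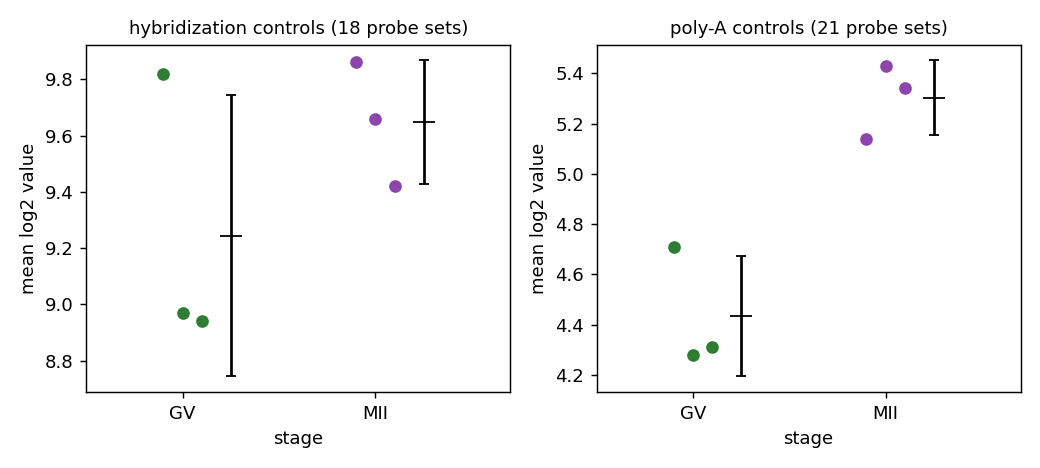
Mean log2 value (y axis, separate scale per panel) of the hybridization controls and of the poly-A controls on each array by stage (x axis), with the mean and SD of 3 arrays beside the points. Poly-A controls are higher on every MII array (5.14 to 5.43) than on every GV array (4.28 to 4.71), whereas the hybridization controls of GV replicate 1 lie within the MII range.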

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

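The tests of a uniform offset and of the poly-A controls relative to the hybridization controls were chosen only after the results they bear on had been seen. The poly-A control features, which are not oocyte genes, were higher on the MII arrays by 0.87 (log2) on average, and they drew attention as a difference between the stages in features outside the main measurement. They were higher for 21 of 21 probe sets, with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 samples can give. The hybridization controls were also higher for 18 of 18 probe sets, and probe sets of 1 control transcript are not independent.

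Called probe sets were mostly lower in MII, 7376 against 2358. A uniform offset between the arrays of the stages was weighed as the cause of that majority. With array medians made equal 26.4% of called probe sets were lower, and 38.9% after quantile normalization. The share was 98.6% with hybridization and 99.6% with poly-A controls made equal. Every array held the same set of values, with the same lowest and highest value. This argues against an offset added to all deposited values of an array. The scalings differ in direction, so a shift that left the extremes in place cannot be told apart from a general fall. The unknown rule that kept part of the array's probe sets could also bear on this majority and was not tested. The differences also had a longer tail below their median (median -0.15, with 5% of probe sets below -2.60 and 5% above 0.71), which an offset leaves as it is, so unequal change between probe sets remains under any offset. A smaller share of mRNA in the MII total RNA may contribute, since a fixed amount of control would then be amplified with less competition. Poly-A relative to hybridization controls were higher by 0.47 in MII (2-sided exact permutation p = 0.3), with the arrays of the stages overlapping. That mean took in dim poly-A probe sets beside brighter ones, with rises from 0.25 (phe, 5' end) to 1.47 (thr, 3' end). Single poly-A probe sets were not taken relative to the hybridization controls, so the overlap holds for the mean alone. A smaller share of mRNA could not be told apart from a difference in the controls added, and a change of the oocytes' transcripts during maturation stays open as well. Of the 10 splits of the samples 3 against 3, 1, the real one, called as many probe sets (9734, the highest other 0), and 3 gave as many gene lists (5, the highest other 5). With 10 splits no share under 0.1 is possible. The other splits mix the stages, so the stage difference widens their spread, and 0 calls in them does not measure chance. They still gave 2 to 5 gene lists each at camera's preset correlation. Each of them keeps part of the stage difference, so these list calls may be that difference diluted. The splits therefore cannot show whether lists are called without it.

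Of 10 granulosa and cumulus markers 7 fell in MII as deposited (limma's camera, Benjamini-Hochberg adjusted p = 0.15), with Gja1 at -3.74 (other probe sets -0.93 to -2.36) and Inhba at -1.40, while limma called 0 of 9 cumulus expansion and 0 of 3 theca and stroma genes (0 unadjusted in both). In those 2 lists 0 genes had a mean above the median of all probe sets, so they are a weak contrast. Follicle cells left on the GV oocytes, from which cumulus cells had been removed by pipette and not with hyaluronidase as for MII oocytes, are a candidate explanation. The list's median of -0.54 lay at percentile 8.94 of 10000 random lists matched on level, neither below the 2.5th percentile set for that explanation nor above the middle, so it cannot be told apart from a general fall at this level or from a fall within the oocyte. In GV oocytes 5 of the 10 markers were above the median level of all probe sets.

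Probe sets of 1 gene were called in opposite directions for 513 of 4739 genes with several probe sets (10.8%). Without the probe sets of the types _s_at and _x_at, taken as those that match several transcripts, the share was 11.5% (438 of 3818 genes). These types alone therefore do not account for the opposite calls, while the type _a_at was kept and was not tested. Without dim probe sets the share was 14.2% (334 of 2350 genes). Since the genes compared also changed, this cannot decide whether dim probe sets contributed. Shuffling probe sets among genes gave 698 to 814 such genes, more than the 513 observed, which argues against probe sets of a gene being unrelated. Alternative ends or transcript forms that change differently may explain part of the 513 and were not tested, and no probe positions were used here.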

How the results depend on the processing

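The scaling on poly-A controls was chosen after seeing the data. The 2358 higher and 7376 lower probe sets (332 and 4454 by 2-fold or more) became 12016 and 4306 (3138 and 2672) with array medians subtracted, 7538 and 4794 (2350 and 2900) after quantile normalization, and 104 higher (62 by 2-fold) with hybridization controls made equal, where 7179 were lower. With poly-A controls made equal they became 65 and 18380 (4 and 11241). With dim probe sets left out, fewer were tested, and 4438 were lower (2969 by 2-fold). With no moderation 1279 were higher (212 by 2-fold), and at the stricter threshold of 0.01, by construction fewer, 1080. With each sample left out, higher probe sets numbered 1547 (without GV replicate 2) to 2127, lower ones 6668 to 6958, those at least 2-fold higher 230 to 470 and 2-fold lower 4404 to 4558. Array weights (0.768 to 1.22), an intensity trend with robust moderation, leaving out probe sets matching several transcripts and the replicate block kept every one of these counts within 1.5 times. By limma's equivalence test with Benjamini-Hochberg adjustment the stable probe sets, 0 (3108 unadjusted), became 530 with a trend and robust moderation, 256 with no moderation, 852 with array weights and, by construction of the wider bound, 5825 at 2-fold. The 5 gene lists became 0 with camera's estimated correlation (1 of the 5, cytosolic ribosomal proteins, at an unadjusted p under 0.05), and numbered 5 to 7 in the scalings, filters, trend, weights, block and mean over probe sets and with each sample left out. By fry 30 lists were called, but fry tests a list against no change and not against the other genes, which is another question. Apart from the changes shown by construction, the cause was not tested.

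With the replicate number as a block, 2400 probe sets were higher and 7300 lower. Same-numbered samples correlated at 0.091, 0.029 and 0.027 after stage means were removed, and no sample correlated best with its own number, a hint that the numbers do not pair the samples.

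Some of the 139 named genes and of the lists (mean difference from other genes) changed sign, and the cause was not tested. With array medians subtracted these were Cyp11a1 0.17, Star 0.49, Col1a2 0.61, Mfap5 0.49, Dazl 0.60, Gpr3 0.15 and Nlrp5 0.32. After quantile normalization they were Cyp11a1 0.03, Star 0.28, Col1a2 0.44, Mfap5 0.26, Dazl 0.28, Gpr3 0.13 and the oviduct list -0.06. The hybridization controls were at 9.82 on GV replicate 1 and at 8.97 and 8.94 on the other GV arrays. Making them equal widened the spread within the GV stage, which can end calls by itself. With hybridization controls made equal the genes that changed sign were Gdf9 -0.32 and Pde3a -0.17, and 43 named rises lost their call. With poly-A controls made equal, as an array shift, they were Cox8a -0.33, Mrpl40 -0.31, Psmd3 -0.19, Cnot8 -0.11, Cnot2 -0.12, Tent2 -0.38, Marf1 -0.46, Racgap1 -0.05, Tpx2 -0.39, Bmp15 -0.18, H1f8 -0.21, Prkaca -0.07, Cks2 -0.05, Kif23 -0.19, Gtf2a2 -0.16, Srsf3 -0.17, Snrpg -0.30, Rcc1 -0.25, Nup37 -0.33, Hspa14 -0.24, Ski -0.28, Mapkapk5 -0.17, Rps6kb2 -0.03, Csnk1e -0.15, Actb -0.44, Gdf9 -0.79, Hprt -0.32 and Pde3a -0.64, and 19 further rises lost their call. Without dim probe sets the glycolysis list was at 0.08, spindle at 0.06 and granulosa at 0.02. Without probe sets matching several transcripts Supt20 was at 0.55, Elp2 at 0.31, Tob2 at 0.44 and the oviduct list at -0.04. The mean over probe sets gave Sars -0.30, Terb1 -1.42, Sdhd -0.35, Cnot2 -0.71, Racgap1 -0.51, Camk2g -0.50, Pold3 -1.44, Mcm5 -0.83, Rad51c -0.32, Hsp90b1 -0.72, Ski -0.51, Ctnnbip1 -0.09, Csnk1e -0.19, Star 0.06, Actb -0.02, Dazl 0.17, and the lists of decay -0.11, spindle 0.07 and nuclear pore 0.03. Under that mean 6 further named rises and 2 falls kept their sign but lost their call. With 1 sample left out, Col1a2 was at 0.01 to 0.06 without GV replicate 2, MII replicate 1 or MII replicate 2, Dazl at 0.13 without MII replicate 2, and the spindle list at 0.01 without GV replicate 2 or MII replicate 1. With no moderation 19 named rises and 1 fall lost their call. Signal limits the falls: 37 of the 70 named falls ended below the median of every MII array, and no measure of background was used here.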

Other observations

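The groups given here, and their tests, were chosen only after the data had been seen. Among 115 groups of at least 10 genes, families sharing the start of their symbol and the aminoacyl-tRNA synthetases, 7 were called by limma's camera after Benjamini-Hochberg adjustment (Rpl, Rps, Mrpl, Mrps, Ndufa, Ndufb and Atp), and the adjusted p of each was 0.91 with an estimated correlation. That version called 0 of the 115 groups. Within the Atp family, 14 of 17 ATP synthase genes fell (14 in the 3 other scalings set beforehand and 17 with poly-A controls made equal), as did 11 of 18 genes of the vacuolar proton pump (7 with array medians made equal, where 5 rose, 7 after quantile normalization, where 3 rose, and 18 with poly-A controls made equal), with Benjamini-Hochberg adjusted p of 4.1e-05 and 0.018 by limma's camera and 0.16 with an estimated correlation for both. Of 25 other Atp genes 11 fell (10, with 11 rises, with array medians made equal), with a Benjamini-Hochberg adjusted p of 0.38 by limma's camera.

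Of 5 genes of the subcortical maternal complex 4 fell in each of the 5 scalings, Khdc3 (-3.48), Padi6 (-2.24), Tle6 (-2.22) and Ooep (-1.99), while Nlrp5 was at -0.30 (0.32 with array medians made equal, -1.18 and called lower with poly-A controls made equal). Padi6 had a GV mean of 13.16, near the top of the arrays' range, so its fall is a lower bound. The 3 zona genes fell in each of the 5 scalings, with Zp1 at -1.26. By limma's camera the Benjamini-Hochberg adjusted p was 0.012 and 0.013, and 0.24 with an estimated correlation for both. Aminoacyl-tRNA synthetases went both ways, 4 of 15 rising and 6 falling (9 and 6 with array medians made equal, 8 and 6 after quantile normalization, 1 and 6 with hybridization and 1 and 11 with poly-A controls made equal), among them Eprs at 1.18, Kars at 1.12, Hars at -3.40 and Mars1 at -3.10 (camera in limma, Benjamini-Hochberg adjusted p = 0.38).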
